A study of Oreochromis niloticus with 21 samples.

How the data were processed

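RNA from 7 tissues of the Nile tilapia (Oreochromis niloticus), a warm-water fish, was sequenced after 12 h at 28, 18 or 10 °C, per the labels. Brain, gill, heart, kidney, liver, muscle and spleen each gave 1 library at each of the 3 temperatures, 21 libraries in all. The labels do not say how many fish were used or whether 1 fish gave several tissues. The zebrafish part named in the series title was not analysed here.

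The deposited files hold 1 RPKM value (reads scaled by gene length and by library depth) for each of 17098 Ensembl gene IDs, per the file headers. TopHat, Bowtie and HTSeq are named in the submitters' processing notes. Their versions and roles, the genome build and the annotation are not given in the sources used here. No ID could be paired with a gene symbol: 0 of the IDs matched the RefSeq table provided, so genes appear by ID, at most 2 higher and 2 lower in each comparison. The lists of pathway genes and cell type markers that were fixed before the data were examined were written as symbols and could not be tested.

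Each RPKM value equals whole reads divided by gene length and by a number specific to the library. Solving for these gave whole reads in 100% of values, within 1e-06, for 17079 genes, and no solution for 19. The solver was tested on simulated data of 3000 genes in 12 libraries, where 99.7% of genes were solved. The implied lengths had a median of 2647 bp, and 44.9% were multiples of 3. The implied denominators were not whole numbers, within 0.001, in any of the 21 libraries. They were 2.29 to 2.73 times a trimmed-mean library size computed from the reads. Recovered reads per library ranged from 248860 to 3560372, and the summed RPKM of a library from 92011 to 1028634. The recovered reads served to give depth, shares and counting error; PCR duplicates could not be recognised, so the intervals cover counting error only.

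The planned test for counts was replaced by the one planned for normalized values. limma 3.58.1 in R 4.3.3, with a mean-variance trend, was fitted to log2(RPKM + 1). A fold change on this scale understates the change of low genes. Genes needed an RPKM of 1 in at least 3 libraries, which left 15312. The first model held tissue as a block and temperature as 3 levels, and compared 10 with 28 °C, 18 with 28 °C and 10 with 18 °C. The second model gave each tissue its own slope on temperature, with 7 residual degrees of freedom, and tested each slope and the difference between slopes. Both were fixed before the data were examined. A comparison of each tissue with the mean of the other 6 was added afterwards. Spread between those 6 tissues does not enter its p-values. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 1 library for each tissue and temperature, the p-values of the first model measure how alike the change was over tissues and not over fish. In the slope model the residual holds departures from a straight line as well as spread between fish. The 3 libraries of a tissue in the tissue comparison come from 3 temperatures and are not replicates.

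Within a tissue no test was possible between 2 single libraries. Genes with an RPKM of 5 in at least 1 of the pair were counted as differing when log2(RPKM + 1) differed by 1 or more, which is 2-fold. The share that counting error alone gives was drawn 20 times from a level common to both libraries. Genes were called enriched in a tissue when their mean there was 4-fold above the highest other tissue; these lists were chosen on the same libraries. Their median fold change was placed among 10000 random lists matched on expression.

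The fits were tested on simulated data. Across tissues at 10 against 28 °C, the simulation held 15309 genes, with 50 of them changed at each fold size. Of these, limma recovered 12% of genes changed 2-fold, 66% changed 4-fold, 88% changed 8-fold and 86% changed 16-fold. There were 3 false calls among 129. The rates are for those changed genes and not for all 15309. They say nothing about the recovery of low genes or of changes that differ between tissues. The simulated values spread less about the tissue means than the real ones, with a median SD of 0.370 against 0.426, so these rates are likely too high for the data. The slope test did less well: in kidney it recovered 0% of genes changed 2-fold or 4-fold, 8% at 8-fold and 22% at 16-fold. Its rates say nothing about low genes either. In simulated data with no change, the slope test called a median of 89 genes in brain and 54 in liver. The median was 36.5 in muscle, 12.5 in gill and 8 in kidney.

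Where no gene passed across tissues, the rule for naming took the 10 smallest p-values; slopes were named by the highest and lowest fitted change among called genes in temperature order. ENSONIG00000002856 was named in addition, after its values were seen, because it took the largest share of reads. Alternatives covered scaling, filters, pseudocounts, limma-voom on the recovered reads, the tissue block, leaving out each tissue, correction for gene length, a first component as a covariate, library weights and leaving out 3 or 4 libraries that stood apart. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.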

Results

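The transcriptomes of 7 tilapia tissues were compared between fish kept for 12 h at 28 °C and fish kept at 18 or 10 °C. Depth differed widely. Brain at 10 °C had 248860 reads on genes and muscle at 18 °C had 3560372, and the median detected gene had 5 to 40 reads. Liver libraries listed 10074 to 11377 genes above 0, and brain libraries 13207 to 15266. There were no replicates within a tissue and temperature.

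Tissue set the main pattern of expression. Each of the 21 libraries had its closest library within its own tissue, by Spearman's rho across genes, which are not independent replicates. Brain at 28 and 18 °C were the most alike, with a rho of 0.928, whereas brain at 10 °C reached 0.731 with its closest partner. In heart, the 28 and 10 °C libraries had a rho of 0.881 and the 18 °C library 0.761 at best. In liver, the 18 and 10 °C libraries had a rho of 0.806 and the 28 °C library 0.716. In gill, likewise, the 18 and 10 °C libraries had a rho of 0.918 and the 28 °C library 0.828. Muscle had no close pair, with a rho of 0.771 between 28 and 10 °C, 0.755 between 28 and 18 °C and 0.732 between 18 and 10 °C. Heart at 18 °C lay nearly as close to spleen at 28 °C, with a rho of 0.743.

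**Figure D1:**
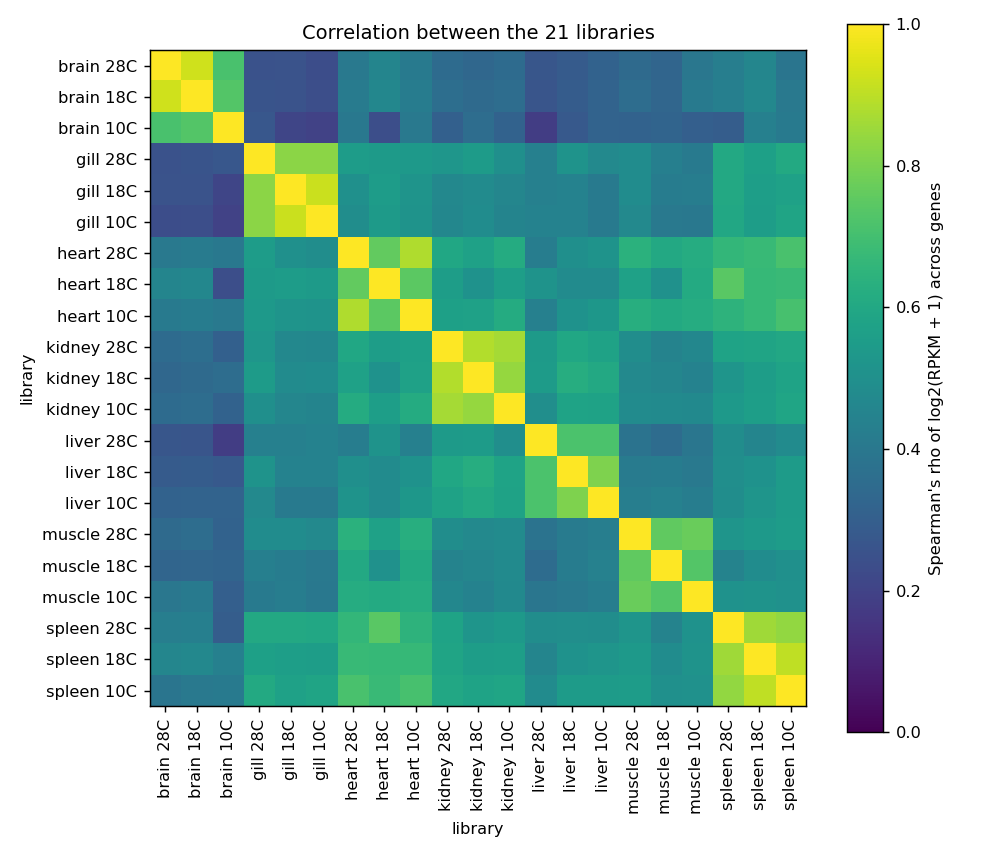
Spearman's rho of log2(RPKM + 1) across genes between the 21 libraries, ordered by tissue and temperature on both axes, with colour giving rho. The 7 tissues form blocks along the diagonal. Brain at 10 °C, heart at 18 °C and liver at 28 °C have a lower rho, a darker colour, within theirs. All muscle pairs are about as low, at 0.732 to 0.771.

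When each tissue was set against the mean of the other 6, liver had 1921 genes higher and 4939 lower (limma, 15312 genes tested). Of the lower genes in liver, 270 were at least 4-fold lower. A gene high in 1 other tissue lifts that mean, so a call does not mean a difference from each other tissue. Brain had 3025 higher and 2501 lower, and 1148 of its genes were at least 4-fold higher. Gill had 2489 higher and 2488 lower, muscle 1770 and 3568, spleen 1644 and 2902, kidney 1928 and 1756, and heart 1333 and 1863. The most enriched gene of muscle, ENSONIG00000019825, was 13.78 higher on the log2 scale (SE 0.52, limma adjusted p = 1.02e-12). Its RPKM was 27550 ± 11680 (SD over the 3 temperatures, n = 3) against at most 13.9 elsewhere. Liver's ENSONIG00000017080 was 13.24 higher (SE 0.62), and brain's ENSONIG00000004362 was 10.45 higher (SE 0.63). In heart ENSONIG00000020926 was 10.70 higher (SE 1.19), in kidney ENSONIG00000014371 was 9.04 higher (SE 0.92) and in gill ENSONIG00000018806 was 7.66 higher (SE 0.53). Spleen's ENSONIG00000001457 was 6.22 higher (SE 0.84). Its RPKM was 26570 ± 19160 (SD over the 3 temperatures, n = 3), with a median of 387 in the other tissues. With the filter of an RPKM of 1 in all 7 libraries of a temperature, which drops genes of single tissues, the counts were 288 in heart to 1604 in liver. The order of tissues depended on the setting: limma-voom on the recovered reads gave 4912 genes in gill, 4770 in brain and 3438 in liver, and without brain at 10 °C, heart at 18 °C and liver at 28 °C there were 6683 in muscle, 6479 in gill and 6274 in liver. Scaling also moved the balance, to 1630 higher and 1951 lower in kidney with median-of-ratios scaling and to 3166 and 2231 in gill with the upper quartile.

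Across the 7 tissues, no gene passed the test at 10 against 28 °C (limma, smallest adjusted p = 0.244). At an unadjusted p under 0.05 there were 1120 genes, 272 higher and 848 lower at 10 °C. Scaling within each tissue made this 427 higher and 665 lower. The count moved both ways with the setting, to 219 without the tissue block and 1393 without muscle. It was 496 with an RPKM of 1 required in all 7 libraries of a temperature, which tests fewer genes. limma-voom on the recovered reads also called 0 genes, and 9 when libraries were weighted by quality, a setting chosen after the data were seen. Genes higher at 10 °C in all 7 tissues numbered 72 and genes lower in all 7 numbered 209, together 1.84% of those tested. The same share was 0.81% at 18 against 28 °C and 0.97% at 10 against 18 °C. Even odds in 7 independent tissues would give 1.56%. Genes at 0 in both libraries of a tissue cannot count, so that value is no fair baseline. The gene with the smallest p, ENSONIG00000008699, was 1.79 higher at 10 °C on the log2 scale (SE 0.30, limma adjusted p = 0.244) and higher in 7 of 7 tissues. Its RPKM went from 17.2 to 60.5 in spleen, from 9.57 to 19.3 in brain and from 1.02, which was 5 reads, to 17.9 in liver. ENSONIG00000004738 was 1.05 higher (SE 0.20, limma adjusted p = 0.318), also in 7 of 7 tissues, but had at most 27 reads in any library and, in liver, 0 reads at 28 °C and 1 at 10 °C. ENSONIG00000009172 was lower in 7 of 7 tissues, with a log2 difference of -1.20 (SE 0.23), but had at most 6 reads in any library. ENSONIG00000016420 was lower in 6 tissues, with a log2 difference of -1.11 (SE 0.21) and at most 8 reads. None of these 4 genes passed, but ENSONIG00000008699 was among the 9 called by limma-voom with quality weights (adjusted p = 0.00255; over its alternatives 0.00255 to 1.00).

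At 18 against 28 °C no gene passed either (limma, smallest adjusted p = 1.00), and 639 genes had an unadjusted p under 0.05. The latter count also moved, to 81 without the tissue block and 817 without brain. After adjustment, limma-voom called 0 genes, and 9 with library quality weights. ENSONIG00000019377 was 0.64 higher at 18 °C (SE 0.16), in 7 of 7 tissues, with at most 48 reads. ENSONIG00000001618 was lower in 7 of 7 tissues, with a log2 difference of -1.17 (SE 0.24), though in brain, liver, muscle and spleen this was 1 read against 0. ENSONIG00000021325 was lower in 5, with -1.11 (SE 0.24), and had reads at 18 °C in gill alone, 3 of them. With limma-voom and quality weights it passed (adjusted p = 0.0445; over its alternatives 0.0445 to 1.00). Between 10 and 18 °C no gene passed (limma, smallest adjusted p = 0.934) and 602 had an unadjusted p under 0.05, 233 higher and 369 lower; median-of-ratios scaling made this 296 and 287. The 602 became 72 without the tissue block and 717 without liver. After adjustment, limma-voom called 0 genes, and 1 with library quality weights.

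The fold changes at 18 and at 10 °C correlated across genes with r = 0.566, but both use the 28 °C libraries. Unchanged groups simulated with equal, independent spread and a shared 28 °C group gave 0.501, a value that the sharing alone sets. Their covariance was 0.0663 against a simulated 0.0479, a difference of 0.0184. When the tissues were divided so that no 28 °C library was shared, the covariance averaged 0.0056 over 35 divisions, from -0.0653 to 0.0416. Each division sets 18 °C in some tissues against 10 °C in others, so it also takes out any response shared within a tissue. It cannot tell such a response from the effect of the shared libraries.

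ENSONIG00000002856 took more reads than any other gene. It held 56.3% of reads in muscle at 10 °C (95% exact interval 56.2 to 56.3), 31.7% in muscle at 28 °C and 13.5% in muscle at 18 °C. In kidney it went from 0.165% at 28 °C and 0.497% at 18 °C to 32.7% at 10 °C. In heart the shares were 0.549% at 28 °C, 0.00682% at 18 °C and 6.31% at 10 °C. Brain had 0.00480% at 28 °C and 1.94% at 10 °C, and spleen 0.00308% and 0.470%. In gill it held 11.5%, 18.7% and 20.9% at 28, 18 and 10 °C, and in liver 0.356%, 1.08% and 0.715%. Its share of reads was larger at 10 than at 28 °C in 7 of 7 tissues and its RPKM in 6, liver being lower by RPKM. On the log2 scale the gene was 4.09 higher at 10 °C (SE 1.09), which did not pass (limma adjusted p = 0.557). With limma-voom and library quality weights, chosen after the data were seen, it was 4.13 higher and passed (adjusted p = 0.0426; over its alternatives 0.0426 to 1.00).

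**Figure D2:**
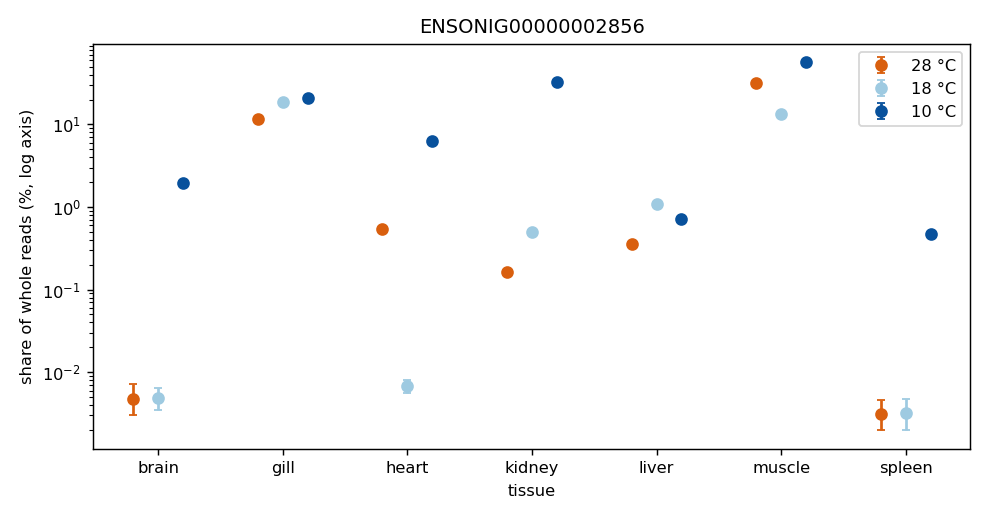
Share of whole reads, in percent on a log axis, taken by ENSONIG00000002856 in each tissue at 28, 18 and 10 °C, with 95% exact binomial intervals for counting error. Kidney goes from 0.165% at 28 °C to 32.7% at 10 °C, while muscle lies between 13.5% and 56.3%.

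Within tissues, the share of genes that differed at least 2-fold between 10 and 28 °C was 65.5% in liver, 53.6% in brain, 42.9% in spleen, 36.6% in gill, 31.7% in muscle, 21.8% in kidney and 15.3% in heart. Counting error alone, which leaves out differences between fish and between preparations, gave 0.350% in gill to 7.29% in muscle. With a pseudocount of 5 in place of 1 the shares were lower, at 48.2% in liver, 28.1% in brain, 20.5% in spleen, 16.8% in gill, 17.9% in muscle, 9.01% in kidney and 4.63% in heart. Between 18 and 28 °C, with a pseudocount of 1, the share was 64.2% in liver and 56.1% in heart but 4.47% in brain, where counting error alone gave 1.39%. The smallest share was found between 18 and 28 °C in brain, 10 and 18 °C in gill, liver and spleen, and 10 and 28 °C in heart, kidney and muscle; by Spearman's rho, kidney's closest pair was 18 and 28 °C (0.883 against 0.866). These differences have no replicate check, so temperature and fish were not separated.

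**Figure D3:**
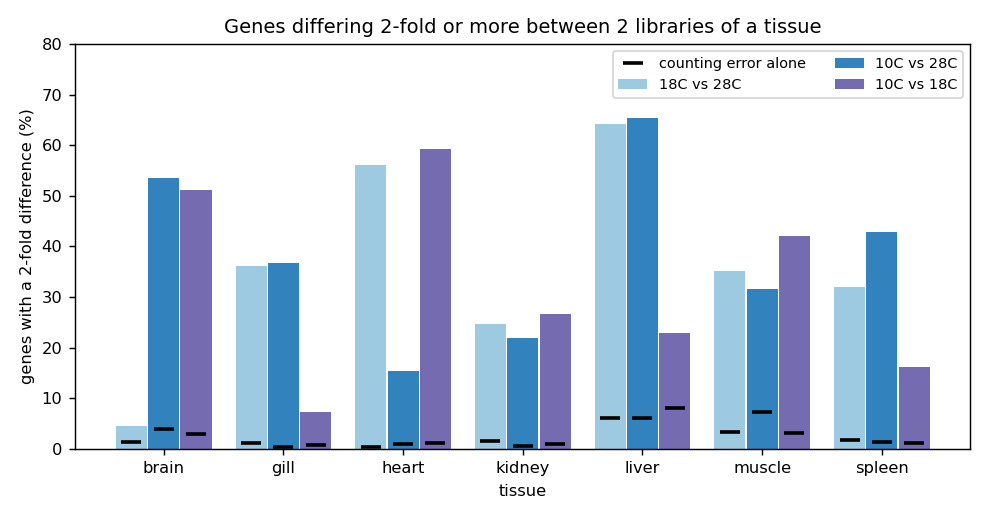
Percent of genes that differed at least 2-fold between 2 libraries of a tissue, as bars for the 3 pairs of temperatures; black dashes give the share from counting error alone. Brain has 4.47% between 18 and 28 °C and 53.6% between 10 and 28 °C.

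Genes enriched in a tissue were set beside random lists of like expression in that tissue. In heart at 18 °C the 125 enriched genes had a median log2 difference from 28 °C of -0.16, against 0.86 for the random lists, and at 10 °C one of -0.15 against -0.11. In liver the median was -1.79 at 10 °C against -1.18, and -1.67 at 18 °C against -1.20. Heart at 18 °C stood apart from the rest of its tissue, as did brain at 10 °C. So did liver at 28 °C, on which both liver comparisons rest, and gill at 28 °C, on which both gill comparisons rest. Liver-enriched genes took 71.7% of liver reads at 28 °C, 54.8% at 18 °C and 58.0% at 10 °C. The 259 genes enriched in kidney had a median of -0.52 at 18 °C and -0.30 at 10 °C, against -0.17 and -0.11 for the random lists. Muscle went both ways, with 0.16 against -0.07 at 18 °C and -0.04 against 0.12 at 10 °C. Genes enriched in spleen lay above their random lists, at 0.39 against -0.22 at 10 °C and 0.29 against -0.19 at 18 °C, and those of brain had -0.38 against -0.65 at 10 °C and 0.11 against 0.07 at 18 °C. In gill the medians were 0.22 against 0.08 at 10 °C and 0.32 against 0.16 at 18 °C. These lists were chosen on the same libraries.

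Gene length went with the differences. At 18 against 28 °C in heart, the shortest 25% of genes, up to 1525 bp, had a median log2 difference of 1.13 and the longest 25%, from 4116 bp, one of -0.78. At 10 against 28 °C the order was the opposite in brain, with -0.97 for the shortest and 0.54 for the longest, and in liver, with -1.39 and -0.08. In liver, however, the library that stood apart is the 28 °C reference. Against their tissue means, heart at 18 °C and liver at 28 °C went the same way with length (rho -0.439 and -0.267). Brain at 10 °C went the other way (rho 0.355). In muscle the medians were 0.09 and -0.07 at 10 °C, and -0.24 and 0.36 at 18 °C. Spleen had -0.39 and 0.67 at 10 °C, and -0.45 and 0.54 at 18 °C. Kidney had -0.23 and 0.08 at 10 °C, and -0.57 and 0.22 at 18 °C. Gill had -0.44 and 0.12 at 10 °C, and -0.27 and -0.02 at 18 °C. The trend was thus not confined to brain, heart and liver.

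**Figure D4:**
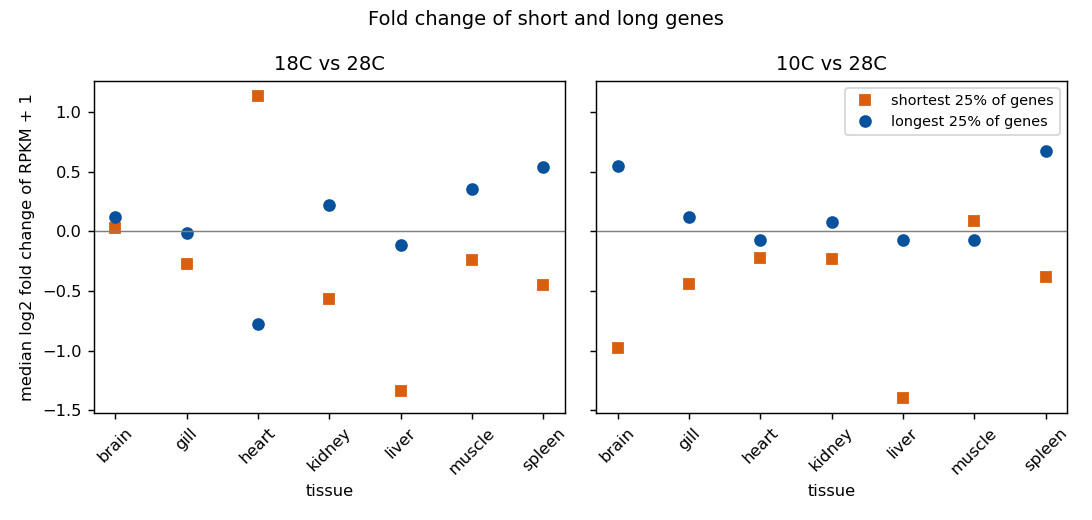
Median log2 fold change of RPKM + 1 for the shortest 25% and the longest 25% of genes in each tissue, at 18 and at 10 °C against 28 °C. In heart at 18 °C the shortest genes lie at 1.13 and the longest at -0.78.

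The fold changes at 10 °C had a median correlation across genes of 0.0555 between pairs of tissues, from -0.173 to 0.437 over 21 pairs. At 18 °C the median was -0.00301, from -0.297 to 0.185. These values cover all tested genes, including those with little or no expression in a tissue. Among genes with a mean RPKM of at least 20 in both tissues, the median was 0.108 at 10 °C, from -0.438 to 0.717. At 18 °C it was -0.0693 in those genes, from -0.478 to 0.338.

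When each tissue was given its own temperature slope, limma called 357 genes in liver, 74 higher in the cold and 283 lower, 300 of them in temperature order. limma-voom on the recovered reads called 52 in liver, 2 in gill and 0 in each other tissue, and after length correction brain also had 0. In liver, ENSONIG00000021006 rose from an RPKM of 5 (3 reads) at 28 °C to 744 at 18 °C and 1588 at 10 °C, and ENSONIG00000014606 fell from 17560 to 1973 and 94.2. ENSONIG00000000044 rose by 7.92 on the log2 scale over 18 °C (SE 0.58), with 1, 10 and 255 reads at 28, 18 and 10 °C, and ENSONIG00000008665 had a log2 change of -7.69 (SE 1.21). Brain had 102 called genes, 63 higher and 39 lower, among them ENSONIG00000012785 with 3.21 (SE 0.46) and ENSONIG00000013853 with -3.96 (SE 0.37). Muscle had 15, gill 13, kidney 7, heart 1 (ENSONIG00000002616) and spleen 1 (ENSONIG00000014556). Data simulated with no change, which spread less than the real data, gave at most 111 calls in brain, 64 in liver, 41 in muscle, 25 in gill, 17 in kidney, 4 in heart and 6 in spleen, and the count in liver alone lay above that range. Other orderings of temperature within tissues gave as many calls in liver in 16 of 100, the real one included, with up to 844. Without brain at 10 °C, heart at 18 °C and liver at 28 °C, liver had 81 and brain 5, and without gill at 28 °C as well, 76 and 12. A tissue that lost a library kept 2, so its slope was then a difference between 2 single libraries. In liver this set 10 against 18 °C, so these counts do not test the slope over all 3 temperatures. The slopes differed between tissues for 5 genes (limma, smallest adjusted p = 0.0241). Among them were ENSONIG00000018138, with a slope of 2.83 in muscle, and ENSONIG00000021062, with 3.43 in gill and -1.91 in muscle. ENSONIG00000011619 and ENSONIG00000017379 had -3.68 and -3.76 in liver. Each of these had a slope of 0 in several tissues. The count of 5 genes is below the median of 30 in data simulated with no change. The call was lost with limma-voom, among genes present in every tissue, without brain, muscle or spleen in turn and without those 4 libraries (limma, smallest adjusted p = 0.0805 in the latter case, and over the alternatives 0.00029 to 1.00).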

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

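The limit for a value far from the other 6 was fixed before the data were examined; in what follows, the tests on mixing and on depth had outcomes stated beforehand, and the others were chosen after the result or a closely related value was seen. Of 36 sets of 7 values, 10 had a value beyond the limit. Chance would give about 1.8 for independent, normally distributed sets. Some of these sets hold the same values and some are of genes named for theirs, so no excess is read from the count.

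Several values set muscle and liver apart from the other tissues. The summed RPKM was 1028634 in liver at 28 °C and 693762 in muscle at 10 °C. Reads over the library's denominator were 0.946 in muscle at 18 °C and 1.76 in muscle at 10 °C. ENSONIG00000002856, the leading gene of muscle at 28 °C, held 31.7% of its reads. Its log2 difference at 18 against 28 °C was -5.74 in heart. The log2 difference of ENSONIG00000009172 at 10 °C was -0.12 in brain, and that of ENSONIG00000019377 at 18 °C was 1.56 in muscle. The correlation across genes of fold change and length was -0.393 in heart at 18 against 28 °C. The slopes differed between tissues for 5 genes, and 19 of 100 orderings of temperature within tissues gave as many, with up to 14, so chance is not excluded.

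Differences within tissues had a main axis, a first component with 37.7% of the variance, whose gene scores had a rho of 0.428 with gene length. It rested mainly on brain at 10 °C, heart at 18 °C and liver at 28 °C, which held 56.3% of the squared scores; their tissues held 84.6%, gill 1.71% and kidney 1.5%. Correcting each library for length left 33.1%, above the 14.5% that the second component held before the correction. This argues against length bias as the whole source, although the second component after the correction was not examined. Depth stays open (r = -0.399 with log2 reads within tissues, exact permutation p = 0.162), as does temperature: the score was higher at 10 °C in 5 of 7 tissues (exact sign-flip p = 0.172). RNA quality was not measured in these data and may also matter.

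ENSONIG00000002856 took a larger share of reads at 10 °C. The authors' denominators were argued against, since the share of whole reads was larger in 7 of 7 tissues. Muscle RNA carried into other tissues would bring other muscle genes: relative to the needed rise, the largest value in brain, gill and kidney was -0.0121, which argues against it there, whereas liver had 3.08, heart 0.109 and spleen 0.247, so it stays open for those; the tissues were separated after these values were seen. The exact sign-flip p over 7 tissues was 0.0156, the smallest the design allows, but the gene was picked for its values and no effect of temperature can be read from it. A response to 10 °C is a candidate explanation, as is a difference between fish or library preparations.

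Brain at 10 °C, heart at 18 °C and liver at 28 °C, picked after their values were seen, stood apart from the other libraries of their tissue. Gill at 28 °C, tested later, lay as far from its pair as liver did by rank correlation (0.828 at best against 0.918). Muscle, where all pairs had a low rho of 0.732 to 0.771, was not tested in this way. A wrong tissue label is argued against, since genes of the own tissue took at least 4.26 times the reads of any other tissue's genes, and 2.04 times in gill. Depth is argued against as the whole source. Thinned to equal reads, the other pair of each tissue had a rank correlation at least 0.118 above those with the library apart. In gill it was 0.0669 above. In brain the thinned values were 0.901 and 0.783, against 0.928 and 0.731 before thinning. The thinned values are from read counts and the others from RPKM, and a part played by depth is not excluded. RNA from another sampled tissue removed at most 14.3% of the squared distance, and 10.6% in gill. Temperature, the fish and RNA quality stay open, untested with 1 library each; the first 3 libraries come from 3 temperatures.

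For the count at 10 against 28 °C, 8 of 64 swaps of the temperatures within tissues gave as many as the real 1120 genes, the highest other being 1718. At 18 against 28 °C it was 28 of 64 (639 genes, highest other 1793), and at 10 against 18 °C 23 of 64 (602, highest other 1483), so chance is not excluded for any of them.

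Tissue differences were not matched by chance: for each tissue only the real arrangement, 1 of 100, reached its count. The highest others were 117 in brain, 866 in gill, 1161 in heart, 140 in kidney, 1222 in liver, 876 in muscle and 2319 in spleen. Of 100 orderings of temperature, those with as many slope calls as the real one numbered 28 in brain (highest other 309), 7 in gill (19), 54 in heart (94), 43 in kidney (17), 16 in liver (844), 37 in muscle (92) and 40 in spleen (6), so chance is not excluded in any tissue. A tissue has only 3 temperatures, and many orderings keep or reverse its real one, so the test had little power to exclude chance.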

How the results depend on the processing

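The gene length correction, the first component as a covariate, library weights, the removal of 3 or 4 libraries or of their tissues, the set of genes present in every tissue, 2 scalings of the slopes (upper quartile and trimmed mean) and the alternatives of the tissue comparison and of the correlation with length were chosen after seeing the data; the rest were fixed before. The count of 0 genes in each temperature comparison across tissues held under every setting fixed before, with limma's smallest adjusted p for 10 against 28 °C between 0.0738 and 1.00. Library quality weights gave 1 gene at 10 against 28 °C, and limma-voom with such weights gave 9 at 10 against 28 °C, 9 at 18 against 28 °C and 1 at 10 against 18 °C. ENSONIG00000002856 at 18 against 28 °C went from -0.61 to -0.96 without kidney and 0.25 without heart as tissues were left out in turn, and to 0.60 without brain 10 °C, heart 18 °C and liver 28 °C, 0.87 without gill 28 °C as well, 0.50 with library weights and 0.46 with limma-voom and weights.

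Slope counts were the least stable. Among genes present in every tissue, liver had 32, and brain, gill, heart, kidney, muscle, spleen and the difference between slopes had 0. After length correction, gill had 4, muscle 8, the difference 1, and brain, heart, kidney and spleen 0. limma-voom gave 52 in liver, 2 in gill and 0 in brain, heart, kidney, muscle, spleen and the difference. Without the 3 libraries, liver had 81, brain 5, kidney 4, muscle 1 and spleen 0. Without gill 28 °C as well, liver had 76, brain 12, kidney 4, muscle 1, and spleen and the difference 0. In these 2 settings the slope of a tissue that lost a library was a difference between 2 single libraries. With no filter, brain had 208, gill 28, kidney 12 and the difference 32. Temperatures scored 0, 1 and 2 gave 155 in brain, 229 in liver, 8 in muscle and 3 in spleen; median-of-ratios scaling gave 4 in kidney and 4 in spleen, upper-quartile scaling 203 in liver and 5 in muscle, and trimmed-mean scaling within tissues 2 in spleen and 8 for the difference. Leaving out each tissue in turn gave 3 to 81 in brain (3 without spleen), 5 to 17 in gill, 0 to 4 in heart, 1 to 12 in kidney, 139 to 499 in liver (139 without gill), 2 to 20 in muscle, 1 to 2 in spleen and 0 to 4 for the difference (0 without brain, muscle or spleen).

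For the tissue comparison, an RPKM of 1 in all 7 libraries of a temperature left 801 genes in brain, 905 in gill, 288 in heart, 394 in kidney, 1604 in liver, 1248 in muscle and 728 in spleen, because fewer genes were tested. limma-voom gave 3438 in liver and 3350 in muscle. Leaving out a temperature, which leaves fewer libraries, gave 2713 to 3829 in gill, 1567 to 1886 in heart, 2043 to 2642 in kidney, 4461 to 4706 in liver, 2414 to 3943 in muscle and 1809 to 2876 in spleen. A pseudocount of 5 lowered the median share of genes differing 2-fold at 10 against 28 °C from 36.6% to 17.9%. Dividing the tissues so that no 28 °C library was shared took the covariance of the cold comparisons from 0.0663 to 0.0056. That division also takes out any response shared within a tissue. The cause of the other changes was not tested. Scaling moved the median of all genes within a tissue by up to -0.38 (muscle at 18 °C, upper quartile), so directions within a tissue depend on it.

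Of the count-based tests intended for raw counts, limma-voom was run on the recovered reads and the others were not run. The gene list tests were not run, since no ID has a symbol, nor was the overlap of called genes, since the tests across tissues called no gene as first fitted; limma-voom with quality weights called a few. Depth limits the low genes: 5 to 40 reads on the median detected gene.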

Other observations

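With ENSONIG00000002856 left out of both the lists and the total, genes enriched in muscle took 63.9%, 73.8% and 68.2% of the remaining muscle reads at 28, 18 and 10 °C. Kidney-enriched genes took 12.3%, 11.2% and 12.3% of the remaining kidney reads, gill-enriched genes 7.11%, 12.8% and 8.98% in gill, and spleen-enriched genes 10.2%, 17.0% and 7.86% in spleen. Each value comes from 1 library, so temperature and fish were not separated. Outside liver, liver-enriched genes took 5.23% of all reads in spleen at 28 °C, 3.58% and 3.51% in kidney at 28 and 18 °C, 3.47% in heart at 18 °C and 0.419% to 3.33% in the other libraries.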
